A study of Caenorhabditis elegans with 2 samples.

How the data were processed

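Chromatin immunoprecipitation sequencing (ChIP-seq) was applied to whole Caenorhabditis elegans of strain OP443. The labels describe transgenic worms that express the transcription factor EYG-1 (gene eyg-1, sequence name Y53C12C.1) as a fusion with eGFP. The strain carries the protein with a GFP and FLAG tag at its C-terminus. Late embryos were collected 4 hours after synchronization by bleaching, and chromatin was sheared by sonication and precipitated with an antibody against GFP, per the labels. The series held 1 group of 2 libraries, given in the labels as biological replicates 1 and 3, so that no comparison between groups and no test across samples was made. The control library that the labels name was not analysed here.

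In all, 4 kinds of peak list were used, each in the ce11 and the ce10 build, per the notes deposited with the libraries. The list of each replicate held peaks and background regions called on 1 library against 1 control. The pooled list held peaks and background regions called on both libraries together. The optimal list held the regions left after a threshold on the irreproducible discovery rate (IDR), which compares the ranks of regions between replicates, and was derived from both replicate lists and the pooled list. Which alignments, or parts of them, were compared for the optimal list is not known here. A peak in it need not rank high in both replicates. The aligner, the peak caller and their versions were not given in the sources used here. The height of each region was the signal value of the authors' peak caller, as deposited, and was used only to rank, filter and describe regions. The statistical score of each region in the replicate and pooled lists was read as the −log10 of a q-value, as deposited by the authors, from the format of the files. Whether the score of the optimal list rests on a q-value or on the IDR is not known here, and it entered no test. The summit was given as an offset in base pairs from the start of the region. No read counts or library sizes were used here, so that the depth of each library is unknown and no interval that needs it was computed. Candidate regions were called without a strict threshold, and a region's absence from a list does not show that the protein was absent.

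Positions are those of the ce11 lists and are counted from 1. The reference was the WBcel235 assembly, which is the same build, with the Ensembl gene annotation. The ce10 lists served only for counts, overlaps, signal correlation and chromosome shares. Many annotated 5' ends of C. elegans genes are sites of trans-splicing rather than of transcription initiation, so that distances to a 5' end are distances to the annotated end.

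The tests below, the gene lists, the motifs and the rule for the genes named were fixed before the data were examined. Replicates were compared over the 519 regions with the highest signal in each list, as many as the optimal list holds, and regions were counted as shared when they overlapped by at least 1 bp. The expected overlap came from 1000 circular shifts of 1 list along its chromosomes, with a one-sided permutation p. The signal of the optimal peaks was correlated between replicates after matching each peak to the nearest summit within 100 bp, with a 95% interval from 1000 bootstrap resamples of the peaks. For all tests of position, the background was 10000 random draws of 519 regions from the pooled list, with two-sided permutation p-values and Benjamini-Hochberg adjustment over the 6 chromosomes, the 6 annotation classes or the 25 gene lists. The smallest two-sided p that these draws can give is 0.0002. Each summit was put in the first class that applied, in the order promoter (from 1000 bp upstream to 200 bp downstream of an annotated 5' end of a protein-coding gene), non-coding RNA gene, 5' UTR or coding exon, 3' UTR, intron and intergenic. A peak was assigned to the protein-coding gene with the nearest 5' end at most 2000 bp from its summit. Motif and 6-mer shares within 50 bp of the summits were compared with windows of the same size centred 300 bp to each side, using Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 9 motifs or over all 6-mers. The test takes all windows as independent. It ignores that each summit is tied to its own flanks and that some optimal peaks overlap one another.

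The 25 gene lists held transcription factor families (homeobox, bHLH, nuclear hormone receptor, T-box, forkhead and GATA), the Wnt, Notch and TGF-beta pathways, axon guidance and adhesion, pan-neuronal, neurotransmitter identity, neuropeptide, ciliary, glial, body wall muscle, pharyngeal, hypodermal and cuticle, intestinal, germline, ribosomal protein, histone, chemoreceptor, heat shock and chaperone, and cell cycle genes. The symbols tomt-1, opt-2 and daf-21 did not match the annotation and were left out. The genes named are eyg-1 itself, the assigned genes of the 20 optimal peaks with the highest signal, up to 4 members of each list with the highest-ranked peaks, genes with at least 3 optimal peaks, and the genes of the 5 highest regions among the top 519 of the pooled list that overlapped no optimal peak.

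The position tests were checked on simulated sets. Among 200 null draws, 1.68% of gene list tests had an unadjusted p under 0.05 and 1% of the sets had any adjusted call, so that the list test was conservative. When 5 candidate regions of a list were added, the list was called in 16% of sets for homeobox genes, 39.5% for ribosomal protein genes, 22% for neuropeptide genes and 10% for nuclear hormone receptors. When 10 were added, these shares were 97%, 100%, 100% and 70%. The promoter test gave p under 0.05 in 4.5% of null sets and in 90% of sets with some of the regions moved to promoters.

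Alternatives fixed beforehand were other overlap rules and list lengths, other matching distances, the 259 strongest optimal peaks, the top 519 nuclear regions of each replicate alone with that replicate's list as background, other promoter and assignment distances, chromosome lengths, circular shifts or all protein-coding genes as background, other motif windows and backgrounds, and the ce10 lists. Circular shifts of the ce10 lists used the chromosome lengths of ce11, extended where a region lay beyond them. After the annotation classes had been seen, the RNA biotype of genes within 100 bp of the summits was added, together with draws matched on GC content in 10 bins or on annotation class, runs without summits near tRNA or snoRNA genes, the overlap of nuclear regions alone, 6-mer counts within subsets of the peaks and against other candidate regions, and motif and 6-mer shares against the candidate region outside the optimal list with the nearest GC content within 50 bp of its summit, 1 per optimal peak and each used once. Mitochondrial regions entered only the overlap and ranks of the replicate lists. Computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.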

Results

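Binding of GFP-tagged EYG-1, a homeodomain protein named after Drosophila eyegone, was mapped in whole late embryos of C. elegans. The list of replicate 1 held 27360 candidate regions in ce11, that of replicate 3 held 24519 and the pooled list 24215, all including background regions by construction. The optimal list held 519 peaks with a median width of 456 bp and a median signal of 91.6, on the scale of the authors' peak caller, between 71.5 and 444.6. In that list, 34 peaks overlapped another peak, and the 519 peaks formed 502 separate spans.

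Most of the strongest peaks lay beside genes of small RNAs. Of the 20 peaks with the highest signal, 8 had a snoRNA gene within 100 bp of the summit and 5 a tRNA gene. The highest peak lay on chromosome III from 8043790 to 8044119, 510 bp upstream of the 5' end of K12H4.5, with a signal of 444.6, and ranked 1 in replicate 1 and 2 in replicate 3. The next lay on chromosome V from 12303482 to 12303795 at the snoRNA genes C51F7.3 and C51F7.4, with a signal of 405.5, 1095 bp downstream of the 5' end of F55C5.17. The peak ranked 3 lay on chromosome IV from 11026051 to 11026322, within 100 bp of the microRNA gene mir-51, and had no protein-coding 5' end within 2000 bp. Genes of snoRNAs also accompanied the peaks assigned to W03C9.1 (chromosome II, 11960659 to 11960982), to the chemoreceptor genes str-56 (chromosome V, 15873835 to 15874111) and sre-23 (chromosome I, 8259453 to 8259696), to Y43F8C.7 (chromosome V, 19643117 to 19643359) and to T02E1.2 (chromosome I, 8224384 to 8224505). Their signals were 321.6, 307.4, 287.6, 245.9 and 202.3. A tRNA gene accompanied the peaks assigned to C04A11.5 (chromosome X, 13665432 to 13665671), ZK1193.2 (chromosome X, 410134 to 410589) and gcy-33, a soluble guanylate cyclase gene (chromosome V, 12001951 to 12002406), with signals of 265.5, 203.5 and 196.7.

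Other peaks among the 20 strongest lay at promoters with neither kind of gene. The peak on chromosome III from 10461191 to 10461417 lay 68 bp upstream of atx-2, the C. elegans ataxin-2 gene, with a signal of 232.9. That on chromosome IV from 390382 to 390567 lay 42 bp upstream of ears-2, a glutamyl-tRNA synthetase gene, with a signal of 227.8. Promoter peaks were also assigned to M01F1.9 (chromosome III, 3499915 to 3500121), T13C5.6 (chromosome X, 6207845 to 6207974) and W01D2.3 (chromosome II, 14804550 to 14805005), with signals of 251.02, 227.6 and 212.3. The remaining peaks of the 20 had no protein-coding 5' end within 2000 bp, and lay on chromosome V from 11314116 to 11314336 and from 8500485 to 8500664, both at snoRNA genes, on chromosome X from 9743435 to 9743890 and on chromosome III from 8678338 to 8678793, both at tRNA genes.

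Optimal peaks were concentrated at promoters and at non-coding RNA genes and were scarce inside protein-coding genes. Of the 519 summits, 285 (54.9%) lay in promoters, against a mean of 33.7% in draws from the candidate regions (central 95% range 29.7 to 37.8%). Because the promoter class came first, it also holds summits at snoRNA or tRNA genes, such as those assigned to sre-23, T02E1.2 and ZK1193.2. The promoter share without such summits was not computed. Non-coding RNA genes held 91 summits (17.5%), 6.15 times the mean of 2.85% in the draws. Coding exons and 5' UTRs held 5 summits (0.963% against 9.72%), introns 54 (10.4% against 28.9%), intergenic sequence 84 (16.2% against 22.1%) and 3' UTRs 0 (against 2.69%). Each of the 6 differences passed the permutation test, with an adjusted p of 0.00024 for all classes but intergenic sequence (0.0008). The unadjusted p of these 5 classes was 0.0002, the smallest that the draws can give. In draws matched on GC content the ratio for non-coding RNA genes was 2.53, still past the test.

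**Figure D1:**
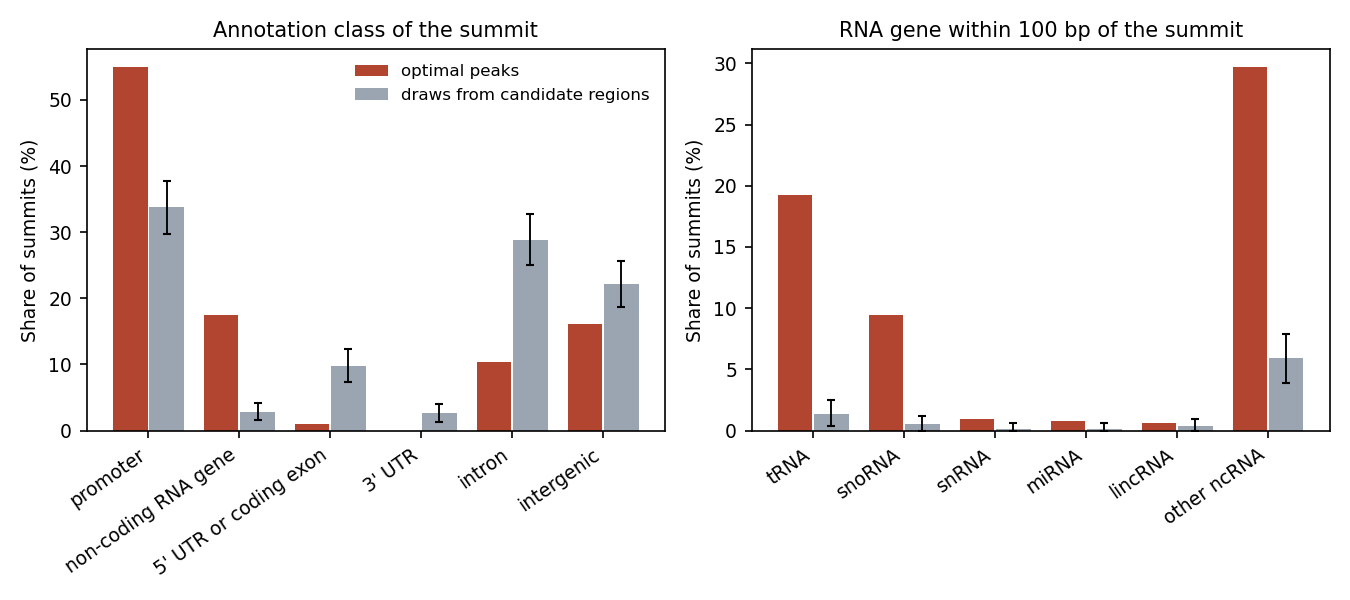
Share of summits, in percent, in each annotation class (left) and within 100 bp of RNA genes of 6 biotypes (right), for the 519 optimal peaks (red) and as the mean of 10000 draws from the candidate regions (grey; bars span the central 95% of the draws). The promoter share of 54.9% and the tRNA share of 19.3% lie above the ranges of the draws.

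Many summits lay on or beside tRNA genes and just upstream of snoRNA genes. A tRNA gene was within 100 bp of 100 summits (19.3%), against a mean of 1.36% in draws, and a snoRNA gene within 100 bp of 49 (9.44%), against 0.509%. No summit was near both. These are ratios of 14.1 and 18.5, with an adjusted permutation p of 0.000667 for each over 10 biotypes. Genes annotated as other non-coding RNA, a heterogeneous class, were near 154 summits (29.7% against 5.91%, adjusted permutation p = 0.000667), small nuclear RNA genes near 5 (0.963% against 0.129%, adjusted p = 0.003) and microRNA genes near 4 (0.771% against 0.159%, adjusted p = 0.0044). Biotypes were not exclusive, and some summits near other non-coding RNA genes were also near a tRNA or snoRNA gene. Pseudogenes were near 3 summits (0.578% against 1.68%, adjusted permutation p = 0.025). The pseudogene call was lost among the 259 strongest peaks (adjusted permutation p = 0.507) and at distances of 0 and 300 bp (adjusted p = 0.131 and 0.0634), and the microRNA call with replicate 1 alone (adjusted p = 0.066) and at 0 bp. Shares for long intergenic RNA, antisense RNA, piRNA and ribosomal RNA genes did not pass the test, except that piRNA genes did within 300 bp (0.771% against 2.42%, adjusted permutation p = 0.0143). In draws matched on GC content the ratios were 5.36 for tRNA and 6.61 for snoRNA genes, 2.11 for other non-coding RNA genes instead of 5.02, and 4.34 for small nuclear RNA genes instead of 7.47. A total of 11.6% of summits lay inside a tRNA gene and 0.963% inside a snoRNA gene. The breakdown by biotype was chosen after the classes had been seen.

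Of the 612 annotated tRNA genes, 105 (17.2%) had an optimal summit within 100 bp, and of the 346 snoRNA genes 49 (14.2%). Summits near tRNA genes had a median position 16.5 bp inside the gene's 5' end (quartiles −10.2 and 42.2 bp). Summits near snoRNA genes had a median position of −47 bp, upstream of the 5' end (quartiles −59 and −31 bp), and 42 of the 49 lay upstream. The median signal was 104.3 near tRNA genes and 144.01 near snoRNA genes, against 87.3 for the 370 peaks near neither.

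**Figure D2:**
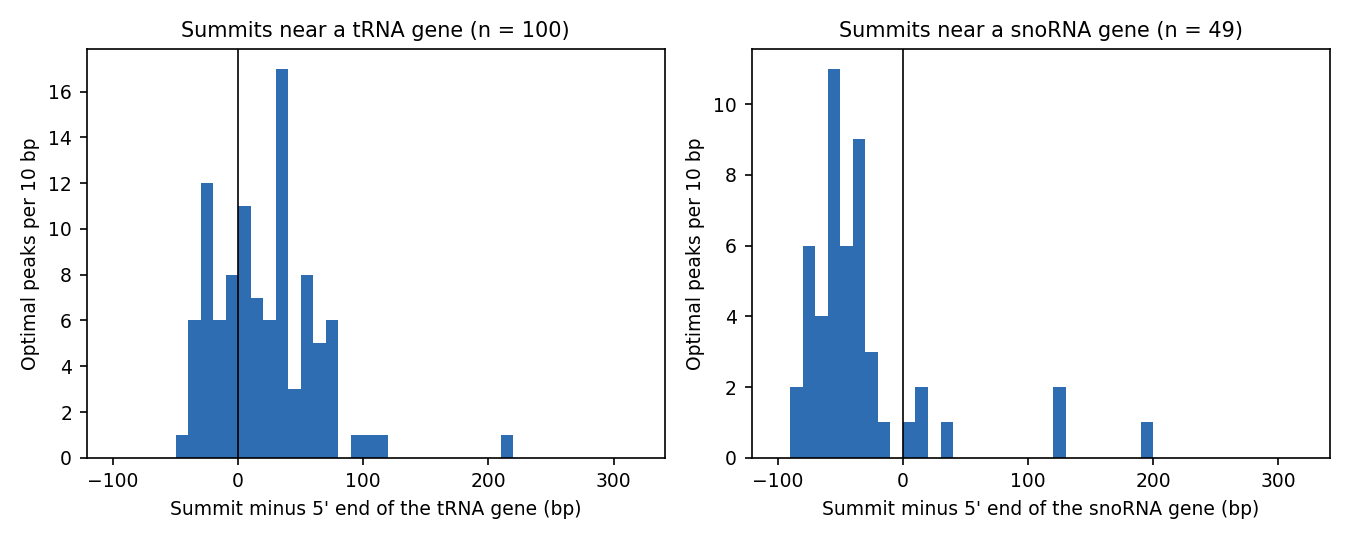
Position of the summit relative to the annotated 5' end, in bp, for the 100 optimal peaks near a tRNA gene (left) and the 49 near a snoRNA gene (right); bars count peaks per 10 bp and the vertical line marks the 5' end. Summits near tRNA genes lie around and inside the gene start, with a median of 16.5 bp, and those near snoRNA genes mostly upstream, with a median of −47 bp.

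Chromosome X carried more optimal peaks than the candidate regions did. It held 135 of 519 peaks (26.01%), against a mean of 16.3% in draws (range 13.3 to 19.5%, adjusted permutation p = 0.0012). Chromosome V held 61 (11.8% against 16.2%, adjusted permutation p = 0.0114). Chromosomes I, II, III and IV held 77, 81, 95 and 70 peaks and did not pass the test (adjusted permutation p = 0.0664, 0.81, 0.625 and 0.177). Against chromosome length instead of candidate regions, chromosome III passed above its share (18.3% against 13.7%, adjusted permutation p = 0.008) and IV below it (13.5% against 17.5%, adjusted p = 0.0255). Of the 100 peaks near a tRNA gene, 55 lay on X, which holds 276 of the 612 tRNA genes (45.1%). Without summits near tRNA genes, X held 80 of 419 peaks (19.1% against 15.9%, adjusted permutation p = 0.181) and the difference on chromosome V did not pass either (12.9% against 16.3%, adjusted p = 0.181). Chromosome V also lost its call among the 259 strongest peaks (14.3%, adjusted permutation p = 0.651) and in draws matched on GC content (adjusted p = 0.132).

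**Figure D3:**
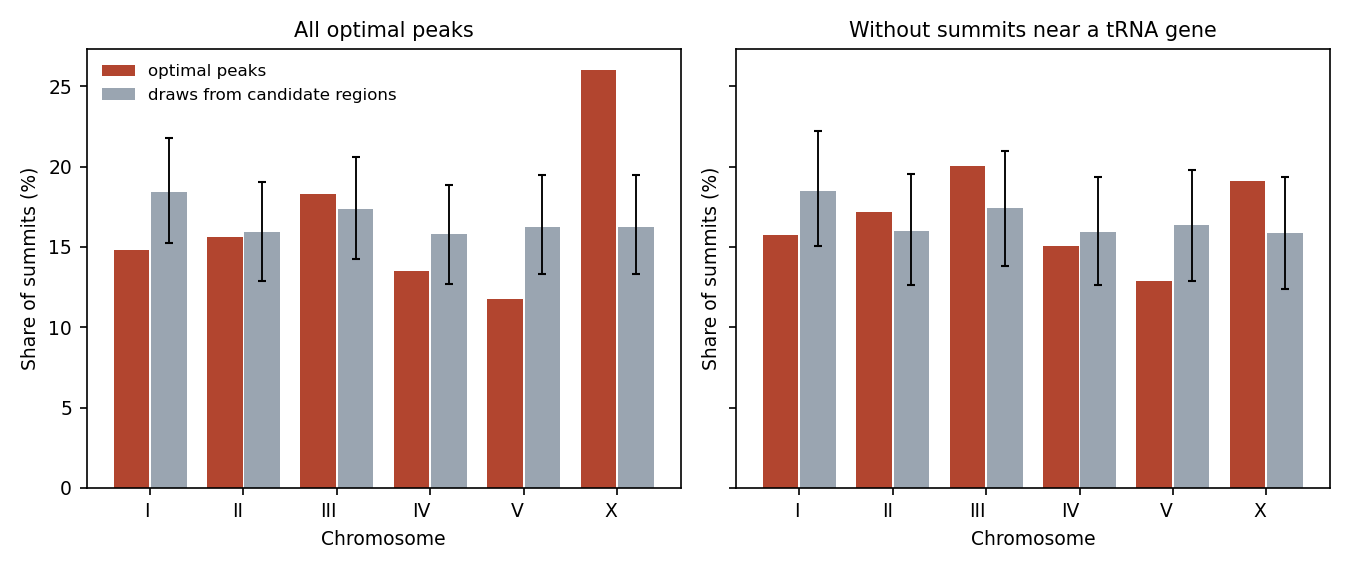
Share of optimal peaks on each chromosome, in percent, for all 519 peaks (left) and for the 419 without a tRNA gene within 100 bp of the summit (right), in red, beside the mean of 10000 draws of candidate regions treated alike, in grey, with bars over the central 95% of the draws. The X share of 26.01% lies above the range of the draws, and the share of 19.1% without tRNA summits lies inside it.

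Along the chromosomes, 286 peaks (55.1%) lay between 25% and 75% of the chromosome's length, against 44.02% in draws (range 39.9 to 48.4%, permutation p = 0.0002, the smallest the draws can give). Per chromosome, central peaks were in excess on chromosome V (45 of 61, adjusted permutation p = 0.0012) and III (56 of 95, adjusted p = 0.0036). On chromosomes I, II, IV and X the central shares of 50.6%, 53.1%, 45.7% and 52.6% did not pass the test.

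Genes of ribosomal proteins had more optimal peaks than drawn candidate regions gave. Of 519 peaks, 390 (75.1%) were assigned to 375 protein-coding genes, at a median distance of 357.5 bp, and 304 of them lay upstream of the 5' end. Among the 81 ribosomal protein genes, 7 were assigned a peak, against a mean of 1.46 in draws (4.79-fold, range 0 to 4 genes, adjusted permutation p = 0.015). The strongest of these peaks lay at rpl-3 (chromosome III, 3867480 to 3867654, 287 bp upstream, signal 163.6), rpl-15 (chromosome IV, 654699 to 655154, 351 bp upstream, signal 130.6), rps-28 (chromosome IV, 1659063 to 1659518, 400 bp upstream, signal 112.4) and rps-24 (chromosome IV, 385118 to 385573, 541 bp upstream, signal 110.1). The other members were rpl-35 (chromosome III, 7854462 to 7854917), rps-1 (chromosome III, 4475392 to 4475847) and rpl-12 (chromosome IV, 13240478 to 13240933), named after their values had been seen. In replicate 3 no summit lay within 100 bp of the rps-1 peak or of the rps-24 peak given above. Another rps-24 peak (chromosome IV, 385349 to 385804) was matched in both replicate lists. None of the 7 genes had a peak within 100 bp of a tRNA or snoRNA gene. The call was lost among the 259 strongest peaks (4 genes, 5.48-fold, adjusted permutation p = 0.32), in draws matched on GC content (3.78-fold, adjusted p = 0.07) and in draws matched on annotation class (3.29-fold, adjusted p = 0.25).

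No homeobox gene was assigned an optimal peak, against a mean of 2.69 in draws, nor was any bHLH (0.765), T-box (0.225), forkhead (0.554), GATA (0.337), neurotransmitter identity (0.368), intestinal (0.308) or germline gene (0.453). None of the 24 lists other than the ribosomal protein genes passed the test, with adjusted p of 0.9999 or 1, and 1 list of 25 had an unadjusted p under 0.05. The test had little power for small excesses, as 5 added regions were called in 10% to 39.5% of simulated sets. It could not call a depletion for the lists at 0. That lowest possible count gave an unadjusted permutation p of 0.12 for homeobox genes and a higher one for the other lists at 0.

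Single members of several developmental lists did have peaks. In the Wnt pathway list 3 genes were assigned a peak against a mean of 1.64: lit-1, a Nemo-like kinase gene that is also on the glial list (chromosome III, 13721099 to 13721554, in an intron), kin-19, a casein kinase gene (chromosome III, 4087622 to 4088077), and vang-1, a planar polarity gene (chromosome X, 2885368 to 2885823). The Notch list had lag-1, the CSL transcription factor gene (chromosome IV, 6097027 to 6097482), against 0.592, and the TGF-beta list had daf-14, a Smad gene (chromosome IV, 10252303 to 10252758), against 0.604. Glial genes numbered 1 against 0.564. Axon guidance and adhesion genes numbered 4 against 3.6, namely unc-115 (chromosome X, 10146518 to 10146973), the ephrin gene vab-2 (chromosome IV, 3763370 to 3763825), the semaphorin gene smp-1 (chromosome I, 14808259 to 14808714) and unc-33 (chromosome IV, 3521010 to 3521465). The pan-neuronal list had unc-33 and syd-2, a liprin gene (chromosome X, 10555382 to 10555837), against 1.08. The ciliary list had daf-19, the RFX factor gene of ciliated neurons (chromosome II, 10169368 to 10169823), against 0.966. Neuropeptide genes numbered 3 against 1.92: nlp-76 (chromosome X, 12665054 to 12665509), flp-23 (chromosome III, 8650251 to 8650706) and ins-13 (chromosome II, 5543466 to 5543921). The first 2 of these peaks lay at tRNA genes and the last at a small nuclear RNA gene. Some peaks named above were not matched within 100 bp in both replicate lists. Those of lag-1 and daf-19 had no such summit in replicate 1, and that of vab-2 had none in replicate 3. Some matched peaks ranked low in 1 or both replicates. The unc-33 peak ranked 4855 in replicate 1 and 1638 in replicate 3, and the daf-14 peak 3852 and 747, in that order. For kin-19 these ranks were 1725 and 413, and for smp-1 they were 108 and 1056.

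Among tissue lists, body wall muscle genes numbered 3 against 1.59, with the attachment genes unc-112 (chromosome V, 14696869 to 14697324) and unc-97 (chromosome X, 5591799 to 5592254) and the myosin light chain gene mlc-3 (chromosome III, 5564735 to 5565190). In replicate 1 the unc-97 and mlc-3 peaks had no summit within 100 bp, and the unc-112 peak ranked 22761 with a signal of 7.88. The pharyngeal list had 3 genes against 2.07, all of the pqn family: pqn-41 (chromosome III, 1921209 to 1921664), pqn-71 (chromosome V, 15464997 to 15465452) and pqn-65 (chromosome X, 4616793 to 4617248). The pqn-71 summit lay within 100 bp of tRNA genes, and the pqn-41 peak ranked 57 in replicate 1 and 2926 in replicate 3. The pharyngeal list took in every gene with a pqn symbol, whatever its tissue, so that the count need not describe the pharynx. Hypodermal and cuticle genes numbered 5 against 3.87, led by the collagen genes col-94 (chromosome III, 10989478 to 10989933) and col-181 (chromosome X, 12105981 to 12106436), wrt-3 (chromosome IV, 9477560 to 9478015) and col-85 (chromosome II, 12494510 to 12494965). These 4 summits lay within 100 bp of a small nuclear RNA gene, a tRNA gene, a snoRNA gene and a tRNA gene, in that order. Chemoreceptor genes numbered 4 against 9.12, with srd-43 (chromosome X, 13306867 to 13307322, at a tRNA gene) and srh-16 (chromosome V, 12291588 to 12292043) beside str-56 and sre-23. The srh-16 peak ranked 1703 in replicate 1 and 288 in replicate 3. Nuclear hormone receptor genes numbered 2 against 4.82, nhr-255 (chromosome X, 15741834 to 15742289) and nhr-41 (chromosome IV, 1387989 to 1388444), both at tRNA genes. The histone list had his-68 (chromosome I, 9988750 to 9989205) against 0.474. Chaperone genes numbered 2 against 0.715, hsp-3 (chromosome X, 6091855 to 6092310) and hsp-1 (chromosome IV, 17278312 to 17278767). The hsp-3 peak had no summit within 100 bp in replicate 3. Cell cycle genes numbered 2 against 1.16, the cyclin E gene cye-1 (chromosome I, 6781614 to 6782069, at a tRNA gene) and lin-23 (chromosome II, 6370137 to 6370592). Chemoreceptor genes passed the test below the mean with replicate 1 alone (0.252-fold, adjusted permutation p = 0.04) and against all protein-coding genes (0.164-fold, adjusted Fisher's exact p = 1e-05). They did not pass with replicate 3 alone (0.568-fold, adjusted permutation p = 0.945). Chaperone genes passed above the mean with replicate 1 alone (6.12-fold, adjusted permutation p = 0.0467) and when every gene within 2000 bp was counted (5.45-fold, adjusted p = 0.0225). With replicate 3 alone the chaperone list did not pass, at 1.34-fold.

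The gene din-1, which encodes a nuclear receptor co-repressor, was the 1 gene with 3 optimal peaks, all on chromosome II: from 11634923 to 11635378 (signal 123.3), from 11619990 to 11620445 (76.5) and from 11634059 to 11634514 (73.2). A snoRNA gene lay within 100 bp of the first 2. The first had no summit within 100 bp in replicate 3. The second ranked 1060 in replicate 1 and 4221 in replicate 3, and the third 1129 and 380. At eyg-1 itself (chromosome II, 9826448 to 9827952, minus strand) no region stood in the ce11 lists. The nearest pooled summits on each side were at 9797476 and 9884991, a gap of 87.5 kb. Whether regions at this locus were filtered out before the lists were made is not known here. How the transgene affected reads at the locus is not known either, so that the gap may not describe binding.

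Summits were rich in GC, and the motif contrasts with the flanks were not past the test against candidate regions of the same GC content. The median GC content within 50 bp of the summits was 51.5%, against 35.6% in the flanks. The homeodomain core TAATTA was present at 8 of 519 summits (1.54%) and in 46 of 1038 flanking windows (4.43%), a lower share at the summits than in the flanks (adjusted Fisher's exact p = 0.00662). The GATA core was also lower at summits (5.01% against 14.2%, adjusted Fisher's exact p = 1.11e-07). The GC box was higher (3.85% against 0.193%, which is 2 of the flanking windows, adjusted Fisher's exact p = 1.11e-07), with a ratio of 20 that was 4.55 within 100 bp and 3.33 against other candidate regions (1.16%, adjusted p = 0.0255). Also higher was the GAGA repeat (3.47% against 1.16%, adjusted Fisher's exact p = 0.00662). Shares of the paired-class dimer (0% against 0.578%), paired-domain core (0.193% against 0.0963%), E-box (31.02% against 29.8%), bHLH-type E-box (2.31% against 1.25%) and forkhead motif (0.771% against 1.45%) did not pass the test. Among the 259 strongest peaks, with fewer summits, the calls for the homeodomain core (1.54% against 4.05%, adjusted Fisher's exact p = 0.248) and the GAGA repeat (2.7% against 0.965%, adjusted p = 0.265) were lost at ratios of 0.381 and 2.8, beside 0.348 and 3 over all peaks. The homeodomain call was also lost without summits near tRNA or snoRNA genes (2.16% against 4.73%, adjusted Fisher's exact p = 0.104), and the GAGA call against other candidate regions (adjusted p = 0.151). Against 1 candidate region per summit with the same GC content, chosen after the data were seen, none of the 9 motifs passed the test and none had an unadjusted p under 0.05: the homeodomain core was at 1.54% of summits against 1.35% (adjusted Fisher's exact p = 1), the GATA core at 5.01% against 6.36% (0.948), the GC box at 3.85% against 2.7% (0.948) and the GAGA repeat at 3.47% against 3.28% (1). Against the flanks the E-box passed the test, higher at summits, in windows of 25 bp to each side (adjusted Fisher's exact p = 0.0274) and with replicate 3 or replicate 1 alone (0.0338 and 0.00818).

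Of 2080 6-mers, 503 were higher and 358 lower at summits than in flanks after adjustment, and 30 were higher and 19 lower against candidate regions of the same GC content. The 10 with the smallest p were AAAATT, AAAAAT, TAAAAA, TTAAAA, TGAAAA and AAATTA, all lower at summits, and GCGCGC, CCGCGC, CGCGCA and CGAGAG, all higher. AAAATT was present at 13.7% of summits and 38.1% of flanks (adjusted Fisher's exact p = 1.61e-21), and GCGCGC at 11.4% and 0.867% (adjusted p = 4.79e-18). In the comparison at the same GC content AAAATT (14.3% of candidates, adjusted Fisher's exact p = 1) and GCGCGC (6.94%, adjusted p = 0.202) did not pass, while CGCGCA (14.5% against 7.71%, adjusted p = 0.0347) and CGAGAG (17.7% against 8.48%, adjusted p = 0.00313) did. The smallest p there belonged to ACCACT (14.3% against 3.47%) and GTTCGA (13.9% against 3.85%), which were also among the leading 6-mers near tRNA genes. These candidates were not matched on annotation class. Near tRNA genes the 6-mer with the smallest p was CGAACC, at 40 of 100 summits and in 2% of the flanks, and in 4% of candidates of the same GC content (adjusted Fisher's exact p = 2.99e-07). As these summits were chosen for lying near tRNA genes, sequence of such genes in their windows follows from that choice.

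Of the 519 strongest regions of replicate 1, 273 (52.6%) overlapped one of the 519 strongest of replicate 3, against a mean of 0.471% in circular shifts (one-sided permutation p = 0.001, the smallest that 1000 shifts can give). Over the 448 optimal peaks matched in both lists, the signal had a Spearman correlation of 0.189 (95% bootstrap interval 0.0907 to 0.29) and a Pearson correlation of 0.444. These are correlations across regions, which are not independent replicates. Over all 4274 candidate regions matched between the lists the Spearman correlation was 0.464. The optimal peaks all had a signal of at least 71.5 in their list, and such a selection can by itself lower a correlation. The values of 0.189 and 0.464 are thus not alike, and the lower one need not mean that the replicates disagree. Among the optimal peaks, 341 ranked within the top 519 of replicate 1 and 357 within that of replicate 3.

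**Figure D4:**
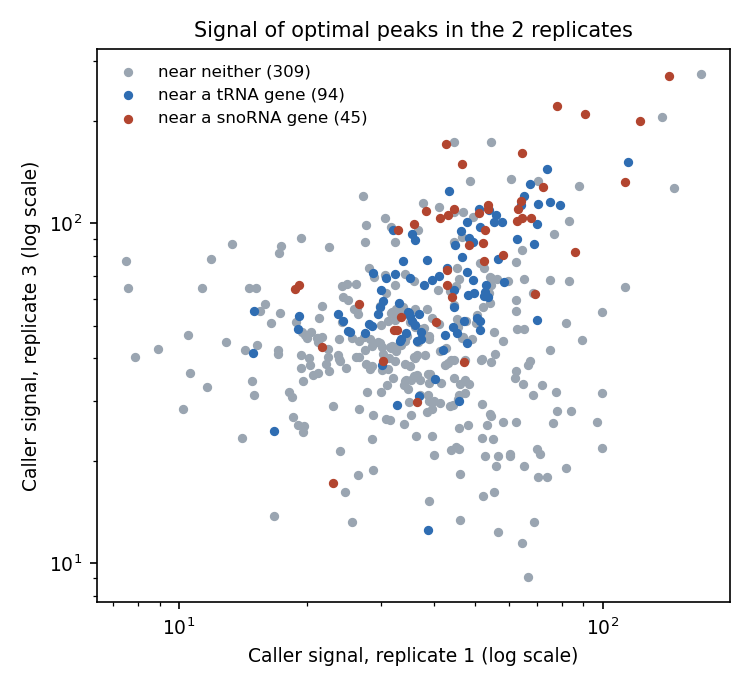
Signal of the authors' peak caller in replicate 1 (horizontal, log scale) and replicate 3 (vertical, log scale) for the 448 optimal peaks matched in both lists, each point a peak, coloured by a tRNA or snoRNA gene within 100 bp of the summit. The Spearman correlation over all points is 0.189.

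Of the top 519 pooled regions, 84 overlapped no optimal peak. The highest lay 209 bp upstream of npp-8, a nucleoporin gene (chromosome IV, 1595805 to 1596260, pooled signal 93.9), 79 bp upstream of fbxl-2 (chromosome III, 4756953 to 4757408, 85.1) and 58 bp upstream of tre-1, a trehalase gene (chromosome I, 6554443 to 6554898, 82.1). The next 2 had no protein-coding 5' end within 2000 bp and lay on chromosome V from 265036 to 265491 (79.8) and on chromosome X from 2227062 to 2227517 (78.6), the latter at a tRNA gene.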

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

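Of the tests in this part, those of the tRNA and snoRNA shares in each replicate and in GC-matched draws, of 31-mers by kind of gene, of the X share without tRNA summits, without GCGCAGGG summits and in GC-matched draws, and of TAATTA at tRNA and snoRNA summits were chosen after the result was seen.

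The list of replicate 3 held 13 mitochondrial regions, outside every test of position, and that of replicate 1 held 0. Of the 13, 10 were among the 519 strongest regions of replicate 3, and the strongest (mitochondrial genome, 12311 to 12492) ranked 1 in that list with a signal of 470.3. No mitochondrial region was in the pooled or the optimal list. Whether such regions were filtered differently from the lists is not known here, so that the contrast need not lie in the libraries.

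Optimal peaks stood at tRNA and snoRNA genes in 28.7% of cases. The tables argue against a signal from 1 library, since with replicate 3 or replicate 1 alone the ratio to the draws was 16.6 and 15.9 for tRNA genes and 21.2 and 19.2 for snoRNA genes. Draws matched on GC content in 10 bins reached 5.2% near tRNA and 2.5% near snoRNA genes at the upper end of their central 95% range, under the observed 19.3% and 9.44%. These draws argue against GC content as the whole cause only as far as the bins match it, because GC was not matched inside each bin. Over all 149 regions a median of 87.8% of the 31-mers were unique in the genome; near snoRNA genes the median was 100% for the regions and for the genes, which argues against reads shared between gene copies there, while near tRNA genes it was 86.9% for the regions, 62% within 50 bp of the summits and 0% for the genes, so that shared reads stay open for the tRNA peaks. Signal of generally accessible or highly occupied chromatin, rather than of EYG-1, cannot be told apart from binding, as no other immunoprecipitation was analysed here and the share of TAATTA decides nothing: it was 0% at these summits against 3.69% of the flanks, which are poorer in GC, and 2.01% of candidate regions of the same GC content (Fisher's exact p = 0.247). The design gives 1 group, and no biological explanation was tested.

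Chromosome X held 26.01% of the optimal peaks. The concentration of tRNA genes on X is a candidate explanation, because without tRNA summits the ratio to the draws fell from 1.6 to 1.2 and the share of 19.1% lay inside the range of the draws (12.4 to 19.3%), with 419 peaks left. Carry-over of binding by the dosage compensation complex, which acts on X, is another for part of the peaks: the core of its recruitment motif, GCGCAGGG, was at 5.19% of X summits (7 of 135) and 0.26% of autosomal summits (Fisher's exact p = 0.000448), against 0.187% of the other X candidate regions; the 7 summits are few, and without all summits that carry the motif X still held 25.05% of the peaks (128 of 511), with a ratio of 1.54. The X share lay above the range of draws matched on GC content in 10 bins (16.6 to 23.1%, mean 19.8%, adjusted permutation p = 0.0036). GC content as the whole cause stays open, because GC was not matched inside each bin. The lower quartile of GC content within 100 bp of the summits was 42.3%, as high as the upper quartile of the candidate regions. Most peaks thus fall in the highest bins. The tables argue against a signal from 1 library, since the ratio of the X share to the draws was 1.54 with replicate 3 alone and 1.36 with replicate 1 alone (adjusted permutation p = 0.0012 and 0.0084).

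The signal in the optimal list was not that of the pooled list, with ratios between 0.685 and 3.39 over the 508 peaks matched within 100 bp (median 1.08) and the same summit for 172. Another weighting of the replicates is argued against for the 447 peaks matched in all lists. There the ratio of replicate 3 to replicate 1 explained 0.0037% of the variance of the log2 ratio of optimal to pooled signal. Peaks with no match in 1 replicate did not enter, so that the test does not cover them. An example is the daf-19 peak, unmatched in replicate 1, with an optimal signal of 87.6 and a pooled signal of 46.9. Other differences in how the lists were made stay open, and no biological explanation was tested.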

How the results depend on the processing

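The runs matched on GC content or annotation class, those without tRNA or snoRNA summits, the overlap of nuclear regions alone, all those on RNA biotypes and those on subsets or matched candidates for 6-mers and motifs were chosen after the data were seen. Depth is unknown, so that its effect on the number of peaks was not judged. No paired analysis was possible because there is 1 group. The share of shared regions stayed above the shifts under 7 alternatives (37.8% to 52.8%), as did the promoter share above its draws under 7 (43% to 66.5%), the non-coding RNA share under 7 (13.3% to 22%), and the tRNA and snoRNA shares under 6 each (11.6% to 25.9% and 0.963% to 15.1%). The optimal list held 551 peaks in ce10. For what follows the cause was not tested, except that fewer peaks or genes enter the shorter lists.

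The Spearman correlation was 0.464 over all candidate regions. Without tRNA summits the X share was 19.1%, and chromosome II turned to 17.2%, above its draws, as it did at 15.6% against chromosome length. The number of gene lists called was 0 among the 259 strongest peaks, 0 in GC-matched draws, 0 in class-matched draws, 2 when every gene within 2000 bp was counted and 2 against all protein-coding genes, and 1 to 3 with a replicate left out. The ribosomal protein fold was 5.48, 3.78 and 3.29 in the first 3 of these. The number of motifs called was 2 among the 259 strongest peaks, where the homeodomain core stood at 1.54% and the GAGA repeat at 2.7%. The homeodomain core stood at 2.16% without tRNA and snoRNA summits, and the GAGA repeat at 3.47% lost its call against other candidate regions. Against GC-matched candidates 0 motifs were called. The shares at summits are then the same and the background changes: the homeodomain core (1.54%), E-box (31.02%), bHLH-type E-box (2.31%) and paired-domain core (0.193%) changed direction, and the GATA core (5.01%), GC box (3.85%) and GAGA repeat (3.47%) lost their calls. The number of 6-mers called, 861 for all peaks, was 272 near tRNA genes, 89 near snoRNA genes, 572 near neither and 553 against other candidate regions, and against GC-matched candidates 49 for all peaks, 18 near tRNA genes, 0 near snoRNA genes and 32 near neither.

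The following changes of direction were of values that passed no test in either setting, apart from the microRNA share, which was 0% at a distance of 0 bp. The antisense RNA share was 0.193% at 300 bp. Among the 259 strongest peaks the folds turned to 0 for Notch, TGF-beta, ciliary and muscle genes, 0.534 for axon guidance and 0.946 for pharyngeal genes. GC-matched draws gave 0.891 for axon guidance, 0.579 for cuticle and 0.566 for histone genes. At 1000 bp they were 0 for Notch, TGF-beta and glial genes, 0.554 for axon guidance and 0.788 for neuropeptides, and at 5000 bp 0.672 for axon guidance, 1.64 for neurotransmitter and 0.786 for ciliary genes. Class-matched draws gave 0.919 for ciliary genes. Without tRNA and snoRNA summits neuropeptides were at 0.726 and cuticle genes at 0.369. With every gene within 2000 bp, cuticle genes were at 0.983 and germline genes at 1.5. With a replicate left out, folds ranged from 0 to 1.68 for Notch, 0 to 1.59 for TGF-beta, 0.907 to 0.975 for axon guidance, 0 to 1.16 for bHLH, 0.639 to 1.53 for muscle, 0 to 1.87 for ciliary, 1.45 to 1.81 for forkhead, 0.993 to 1.52 for cuticle, 0.905 to 1.002 for pan-neuronal and 0.922 to 2.81 for pharyngeal genes. The forkhead motif then stood at 1.16% to 1.35% and the paired-domain core at 0.193% to 0.771%. The paired-domain core was at 0.193% and the E-box at 51.4% within 100 bp, and the paired-domain core at 0.193% against other candidate regions.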

Other observations

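The 6-mer tests in this part were chosen after the data were seen.

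At the 370 optimal peaks near neither a tRNA nor a snoRNA gene, the 6-mers with the smallest p were GCGCGC (14.3% of summits against 0.946% of flanks), CGCGCA (18.1% against 2.43%), CCGCGC (14.9% against 1.49%) and CGAGAG (18.6% against 3.38%), with an adjusted Fisher's exact p of 5.37e-14 or less. GAGAGA was at 27.3% of these summits and 8.78% of the flanks (adjusted Fisher's exact p = 9.23e-13). Against candidate regions of the same GC content GAGAGA (13.5%), CGCGCA (7.03%), CCGCGC (6.76%) and CGAGAG (9.19%) still passed, with an adjusted Fisher's exact p of 0.0393 or less, and GCGCGC did not (7.3%, adjusted p = 0.115). Over all optimal peaks GAGAGA did not pass in that comparison (22.7% against 15.03%, adjusted Fisher's exact p = 0.067). The candidates were not matched on annotation class, so that sequence typical of promoters may pass for that reason. Near tRNA genes CGAACC (40% against 2%) and GTTCGA (42% against 3.5%) led instead, which match the internal B box that tRNA genes carry and passed against GC-matched candidates too (4% each), and near snoRNA genes GCGCCA (28.6% against 0%, adjusted Fisher's exact p = 0.000102), which did not (4.08%, adjusted p = 0.667). The tRNA set was chosen for its nearness to tRNA genes, and the candidates were not. The B box 6-mers thus follow from that choice and tell nothing of EYG-1.

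The gap around eyg-1 was among the larger ones of the candidate lists. Whether regions there were filtered out before the lists were made, and how the transgene affected reads there, is not known here. The gap between neighbouring summits that holds the gene was 87.5 kb in the pooled list, where 5 of 24209 gaps were as large, 40.4 kb in replicate 1 (18 of 27354) and 65.6 kb in replicate 3 (6 of 24500). The median gap was 2277 bp in the pooled list.

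Some optimal peaks ranked low in 1 replicate. Of the 519 peaks, 477 had a summit within 100 bp in replicate 1 and 483 in replicate 3, and the rest were unmatched. All 519 overlapped a region of replicate 3, and 515 a region of replicate 1. Among the peaks matched within 100 bp, 13 ranked beyond 5000 in replicate 1 and 12 in replicate 3. No region of replicate 3 had a q-value of 0.01 or less, against 1126 in replicate 1 and 1347 in the pooled list.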
